A study of Phaeocystis globosa with 6 samples.

How the data were processed

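RNA of Phaeocystis globosa was sequenced on an Illumina HiSeq from 3 colony-stage and 3 single-cell-stage samples. Per the labels' protocols, RNA was extracted with phenol and SDS buffer, treated with DNase and prepared with standard Illumina methods, and a sequencing company carried out filtering and mapping. The submitters' processing notes name RSEM, without a version. The assembler, the reference, its annotation and the read filters are not given in the sources used here. The identifiers have the form Cluster-number.number, which does not name genes.

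Each library has a file with 2 measurements per feature. Per the file headers and the submitters' processing notes, the first is the authors' estimated count of reads per feature (RSEM expected count), not normalized; between 1.71% and 4.16% of the values in a library were not whole. The second is the deposited FPKM, in which the authors divided a feature's reads by its length and by the library's total. All 132211 features are listed in all 6 files, zeros included, so no feature had to be filled in, and 54494 features (41.2%) were at 0 in all 6. The effective length of a feature was recovered by dividing its count by the library total and by its FPKM in the library with the highest FPKM. There were 0 value columns without a sample.

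The main test, fixed before the data were examined, was edgeR 4.0.16 (quasi-likelihood fit and test, two-sided) in R 4.3.3 on estimated counts rounded to whole numbers. Features were kept by filterByExpr, libraries were scaled by TMM, stage was the only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. TMM factors ran from 0.716 in colony replicate 3 to 1.26 in single-cell replicate 1. The common dispersion was 0.538, a coefficient of variation of 73.3% between libraries of a stage. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. The median log2 difference of all tested features was -0.14 with TMM, -0.16 with DESeq2 size factors and -0.31 with library totals only. Single values per library were compared by exact two-sided permutation tests, whose smallest possible p is 0.1 here.

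The test was tested on simulated data, with counts drawn for the 45745 features from the fitted means, dispersions and library sizes of the colony against single-cell comparison. Of 100 features changed 8-fold, 27% were recovered, and of 100 changed 64-fold, 94%, with 4 false calls. With no feature changed there were 0 calls. The simulated features were drawn independently of each other, whereas in these data many features vary together between libraries. The simulation therefore does not measure how many false calls such shared variation gives.

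Features were named by a rule fixed in advance: among those past the threshold, with non-overlapping stages and a mean of at least 10 CPM in the higher stage, the 2 with the largest fold in each direction. This gave 2 higher features and none lower. Gene lists defined by keywords were also fixed in advance (flagella, photosynthesis, carbon fixation, polysaccharides, chitin, adhesion, DMSP and sulfur, nitrogen, phosphorus, calcium signalling, ribosome, proteasome, stress, cell cycle, respiration, lipids and other organisms). They could not be applied because the files pair no identifier with a name, so set tests were not run and markers of other organisms could not be examined.

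Replicate numbers are shared by the stages but the labels tie them to no common culture or day. The numbers were not treated as pairs. The labels give no batch. Alternatives comprised DESeq2 1.42.0 size factors and Wald test, limma 3.58.1 with voom, library totals, no filter and a stricter filter, fold minimums, a stricter p, thinning to the smallest total, features of at least 500 bases, a replicate block and leaving out each library. Added after seeing the data were features with a mean of over 50 counts, normalization within 2 feature sets, the set share as a covariate, leaving out 2 libraries together, and limma on log2(FPKM + 1) with a mean FPKM of at least 1 in a stage.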

Results

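Phaeocystis globosa is a bloom-forming haptophyte alga whose life cycle alternates between free-living single cells and colonies, in which cells sit in a shared mucous envelope. RNA was sequenced from 3 colony-stage samples and 3 single-cell-stage samples, all taken at 10 days in the exponential growth period, to ask which transcripts differ between the stages. The deposited tables list the same 132211 assembled features for every library. These features carry assembly identifiers only, which the files do not pair with gene names or descriptions, so no gene, pathway or cellular function could be assigned to any value below. Estimated read counts summed to 23489419, 20266327 and 22967303 in colony replicates 1, 2 and 3, and to 20090475, 27851325 and 21937944 in single-cell replicates 1, 2 and 3. CPM is a feature's counts scaled to a common library size. A total of 3 counts, taken as the detection floor, corresponded to between 0.108 and 0.149 CPM by library totals alone. The CPM of single features below are also scaled by TMM factors. On that scale the floor is higher in colony replicate 3 (factor 0.716) and lower in single-cell replicate 1 (factor 1.26). Intervals and floors cover counting error only. The labels do not say whether the 3 samples of a stage came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

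A small group of transcripts, with between 1 and 96 counts in each single-cell library, was higher in colony cells in the main test. Whether it passed the threshold depended on the scaling and on single libraries. Of the 45745 features tested with edgeR's quasi-likelihood test, 8 were higher in colonies and 0 were lower at a Benjamini-Hochberg adjusted p under 0.05. Of the 10 ways to part the 6 libraries 3 against 3, the stage split included, 3 gave at least 8 calls, the highest being 24. The number of calls alone thus cannot tell a stage difference from another grouping of the libraries. The fitted differences of the 8 ran from 4.13 to 7.26 on the log2 scale, or 17.6-fold to 154-fold. Together they held 0.0252 ± 0.0271% of the counts in colonies and 0.000909 ± 0.000450% in single cells (SD, n = 3). Without colony replicate 2, the mean share in colonies was 0.00966%. In each of the 8 the 3 colony libraries lay above the 3 single-cell libraries, and colony replicate 2 was the highest library in all 8. With library totals in place of TMM factors edgeR called 0 features, with 1702 under an unadjusted p of 0.05 and a smallest adjusted p of 0.928, although the fitted differences of the 2 features named next were 7.30 and 5.11, against 7.26 and 5.09 with TMM.

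The feature with the largest difference, Cluster-41388.13838, was measured at 7.41, 66.6 and 3.97 CPM in colony replicates 1, 2 and 3. In single-cell replicates 1, 2 and 3 it was at 0.0399, 0.184 and 0.272 CPM, from 1, 5 and 6 counts. Its fitted difference was 7.26 ± 1.11 (log2, SE) with an edgeR adjusted p of 4.29e-05. The effective length implied by its deposited values was 1240 bases. Cluster-41388.28064, with an effective length of 796 bases, had a mean of 21.3 ± 26.2 CPM in colonies and 0.620 ± 0.296 CPM in single cells (SD, n = 3). Its fitted difference was 5.09 ± 0.99 (log2, SE) with an edgeR adjusted p of 0.00947. The identifiers of both begin with a prefix shared by 40081 features, which together held between 94.2% and 96.1% of the counts of each library, so reads could have been divided among related features.

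**Figure D1:**
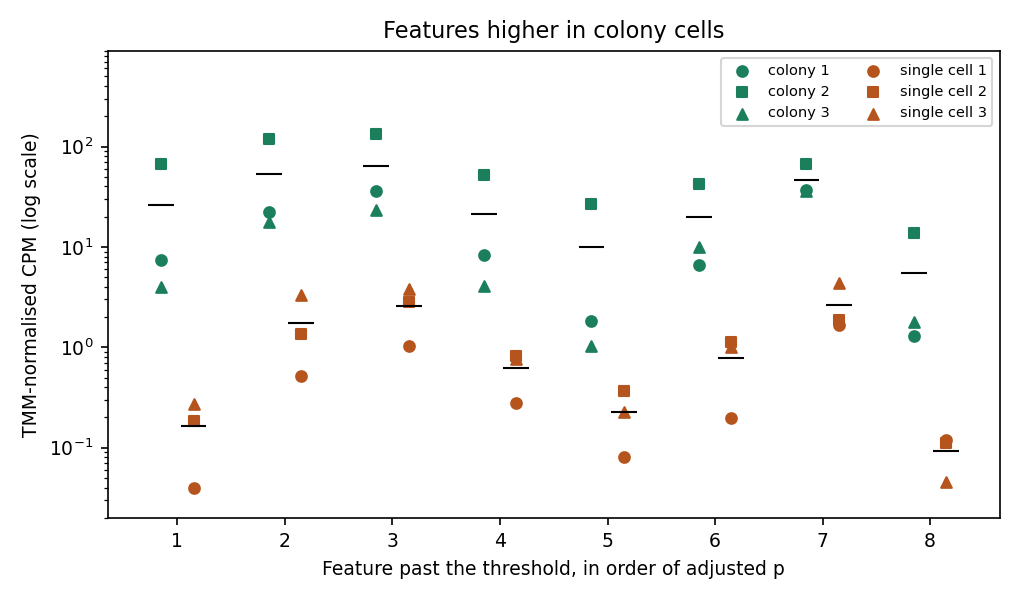
TMM-normalised CPM (log scale) of the 8 features past the threshold, ordered by adjusted p; each symbol is 1 library, green for colony and orange for single cell, the marker shape gives the replicate, and the black lines are group means. In all 8 the colony libraries lie above the single-cell libraries, with colony replicate 2 the highest.

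No feature passed the threshold as lower in colonies in this test, where the smallest adjusted p in that direction was 0.136. At an unadjusted p under 0.05, edgeR gave 1011 lower and 1185 higher features, together 4.80% of those tested. The balance turned with the method: library totals gave 916 lower and 786 higher, and limma-voom 3060 lower and 1310 higher. DESeq2's Wald test called 41 features higher and 19 lower, and limma-voom called 4 higher and 1 lower. DESeq2's calls included 7 of the 8 features and limma-voom's 3 of them. The stages did not overlap for 15.3% of features, of which 2850 were higher and 4171 lower in colonies. The average over all ways to part the libraries 3 against 3 is 10%. As features vary together, a single split can lie far from this average without any stage difference, and the excess was not tested.

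The count of calls depended on single libraries. Leaving out colony replicate 1 gave 23 calls, 15 higher and 8 lower in colonies. Leaving out colony replicate 2 gave 1 call, which was lower, and leaving out colony replicate 3 gave 150, of which 89 were higher and 61 lower. Without single-cell replicate 1 or 2 there were 0 calls, with 1296 or 783 features under an unadjusted p of 0.05. Without single-cell replicate 3 there were 5, of which 1 was higher and 4 lower. The direction of the calls, all higher with the 6 libraries, was thus not kept. The 8 features were all among the calls without colony replicate 1 or 3, 1 of them was without single-cell replicate 3, and none was without colony replicate 2 or single-cell replicate 1 or 2. Both named features stayed higher in colonies without any 1 library, but the naming rule, which required non-overlapping stages, left little room for a reversal. Without colony replicate 2, the fitted difference of Cluster-41388.13838 was 5.04 ± 1.39 (log2, SE) and that of Cluster-41388.28064 was 3.29 ± 1.25, neither past the threshold in edgeR.

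Few transcripts were seen in only 1 of the stages. With at least 10 counts in every library of a stage and 0 in every library of the other, 3 features were seen only in colonies and 12 only in single cells. A count of 0 in a library allows up to 3 counts, or between 0.108 and 0.149 CPM by library totals without TMM factors. Among the other 9 ways to part the 6 libraries into groups of 3, the highest number of such features was 24, and in the other 8 it was at most 8, against 15 between the stages. Without colony replicate 1 or 2 the features seen only in single cells numbered 120 or 70, and without single-cell replicate 3 they numbered 59. Leaving out a library drops a condition, so these numbers could only stay or rise.

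With a minimum of 1 count, more features were detected in each single-cell library than in any colony library, but not with a minimum of 10. At least 1 count was found for 65690 ± 1621 features (SD, n = 3) in single cells and for 57801 ± 9469 (SD, n = 3) in colonies. The exact two-sided permutation test gave p = 0.1 for the difference of -7890 features (colony minus single cell), the smallest value that 3 libraries against 3 allow. Most of the difference lay in colony replicate 3, in which 46886 features were detected, against 63811 and 62705 in colony replicates 1 and 2. Without colony replicate 3 it was -2432 features. With at least 10 counts, 45993 ± 1671 features were detected in single cells and 42210 ± 6411 in colonies (SD, n = 3; exact permutation p = 0.5), and colony replicate 1, at 46753, lay above single-cell replicates 2 and 3. After every library was thinned to the smallest total, the difference was -7543 features (exact permutation p = 0.1). Of the 58664 features with at least 20 counts over all libraries, 10980 were seen in every library except colony replicate 3. The corresponding number for any other library was between 289 and 726.

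The share of counts taken by the most abundant features was compared between the stages by exact permutation tests, none of which can go below p = 0.1. The 10 most abundant features of a library held 5.17 ± 0.577% of its counts in colonies and 5.97 ± 0.181% in single cells (SD, n = 3), with all colony libraries below all single-cell libraries (exact two-sided permutation p = 0.1). This difference of -0.797 percentage points was -0.465 without colony replicate 2 (exact permutation p = 0.2). The 100 most abundant features held 19.8 ± 2.66% and 18.6 ± 0.368%, which did not separate the stages (exact permutation p = 0.8). This difference of 1.17 percentage points became -0.358 without colony replicate 3. The 1000 most abundant held 51.3 ± 6.52% and 47.1 ± 2.02% (exact permutation p = 0.5). That difference of 4.23 percentage points rested on colony replicate 3, where the share was 58.8%, and was 0.475 without it.

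Libraries of the same stage differed widely from each other. The first principal component of log2 CPM held 69.0% of the variance and placed colony replicate 3 at 396.5 and single-cell replicate 1 at -244.4, with the other 4 libraries of both stages between them. Across the 45745 tested features, which are not independent replicates, the Pearson correlation of log2 CPM was 0.957 between single-cell replicates 2 and 3. It was 0.674 between colony replicates 1 and 3, and 0.779 between single-cell replicates 1 and 3. Colony replicate 1 correlated more strongly with each single-cell library, at 0.861, 0.875 and 0.865, than with colony replicate 3. No pair of libraries was a duplicate deposit, as the closest pair, single-cell replicates 2 and 3, had a chi-square of 17.2 per degree of freedom.

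**Figure D2:**
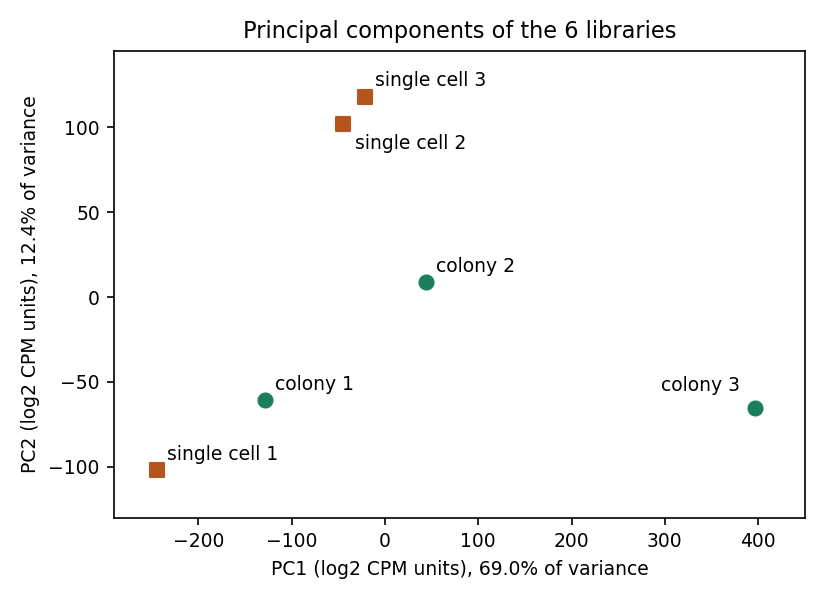
Principal components of log2 CPM over the 45745 tested features, with PC1 on the horizontal and PC2 on the vertical axis, both in log2 CPM units; circles are colony libraries, squares are single-cell libraries, and each point is 1 library. Along PC1, with 69.0% of the variance, the stages overlap, and colony replicate 3 stands farthest out at 396.5.

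The differences between some pairs of replicates fell into 2 groups of features. Among the 28653 features with a mean of over 50 counts, the log2 ratio of colony replicate 3 to colony replicate 1 had 2 peaks, with fitted means of -2.49 and 0.89. The ratio of single-cell replicate 1 to single-cell replicate 3 also had 2 peaks. The ratio of single-cell replicate 2 to replicate 3 had a single peak with an SD of 0.46.

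**Figure D3:**
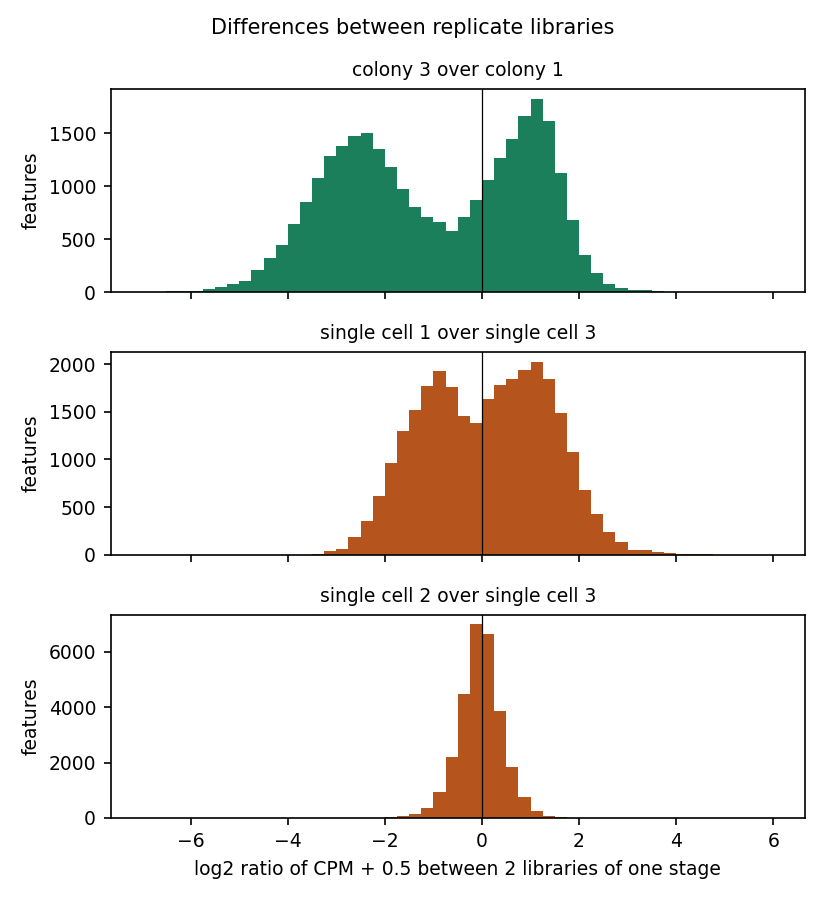
Histograms of the log2 ratio of CPM + 0.5 between libraries of the same stage, for the 28653 features with a mean of over 50 counts; the vertical axis is the number of features per bin, and green and orange bars are colony and single-cell libraries. The upper panels have 2 peaks each, and the lowest panel, with an SD of 0.46, has a single peak.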

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

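The count of 8 features stayed within 1.5 times under DESeq2 size factors in edgeR and a fold minimum of 2 (the same 8 features each), thinning (9, the same 8 and 1 lower in colonies) and a length of 500 bases (8, of which 7 among the original 8 and 1 lower). It was 7 with at least 10 counts in all libraries, of which 3 were lower in colonies and 3 were among the original 8; the filter left only these 3 of the 8 to test. It was 0 with library totals only, 15 without a filter (9 higher, 6 lower), 60 with DESeq2, 5 with limma-voom, 4 with a test against a fold of 2 and 1 at an adjusted p under 0.001. Leaving out 1 library gave between 0 and 150 calls. With the replicate block there were 0 calls, 11.5% of features being under an unadjusted p of 0.05, but the numbers are not known to pair the samples: the deviations of same-numbered libraries from their stage means correlated at 0.617, -0.116 and 0.526 for replicates 1, 2 and 3, and colony replicate 2 did not correlate best with its own number. Among the alternatives chosen after seeing the data, features with a mean of over 50 counts gave 22 calls. Of these, 15 were higher and 7 lower in colonies, and they included the original 8. Normalization within 2 feature sets gave 0, as did the set share as a covariate. Leaving out both colony replicate 3 and single-cell replicate 1 also gave 0. With limma on log2(FPKM + 1) there were 5 calls, 2 higher and 3 lower, and none was among the original 8. The cause of these differences was not tested. The 2 named features were higher in colonies under all alternatives in which they were tested; of their 40 values there, 21 no longer passed the threshold and 19 did. The stricter filter left both out, so it gave no value. The number of features seen only in colonies was 3, and 0 with a minimum of 50 counts, 6 when 1 count was allowed in the other stage, and between 4 and 11 without 1 library. That of features seen only in single cells was 12, and 0 with a minimum of 50 counts, and between 15 and 120 without 1 library. By their definition, both numbers could only stay or rise without a library, and only stay or fall with the minimum of 50 counts. The stage difference in the share of the 100 most abundant features reversed to -0.358 percentage points without colony replicate 3, in a range up to 2.06. Differences in detected features and in the shares of the 10 and 1000 most abundant kept their direction in every alternative run, but not their size: at a minimum of 10 counts the difference in detected features was -3783. No feature was missing from any file and the set tests had no names to use, so alternatives on these points were not run. In simulation, with features drawn independently, the test recovered 27% of 8-fold changes at these depths and dispersions. What limited the number of calls was not tested.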

Other observations

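The tests of life stage, of the sources of RNA and of other splits of the libraries, and the normalization within feature sets, were chosen only after the results they bear on had been seen; the test of length was chosen before its result was seen.

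The deposited transcriptome appears to hold 2 large sets of features whose abundance rises and falls in opposite directions between libraries of the same stage. Together the sets hold nearly all counts, with between 1.38% and 3.98% of a library's counts in neither. On a scale of shares, a fall of one set forces a rise of the other. The opposite directions are thus not a result by themselves, but the scale does not fix which features fall together. A mixture of 2 normal distributions fitted to the log2 ratio of colony replicate 3 to colony replicate 1 put 15659 features in a first set (median -2.53) and 12994 in a second (median 0.92). The same sets separated in single-cell libraries that had no part in defining them: the ratio of single-cell replicate 1 to 3 had a median of 1.00 in the first set and -0.94 in the second, with 87.4% and 87.6% of members on their set's side of 0. The first set held 58.6%, 28.5% and 10.8% of the counts in colony replicates 1, 2 and 3 and 67.5%, 48.3% and 47.1% in single-cell replicates 1, 2 and 3. The Wilson 95% interval for colony replicate 3 was 10.80% to 10.83%. Of the 8 features called higher in colonies, 6 belong to the first set and 2 to the second.

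The tables argue against feature length as the cause of these sets: members of the first set were shorter (median effective length 1166 against 1487 bases), but within 10 length classes 101.5% (median class) of the gap between the sets in single-cell libraries was left. The first set's share did not separate the stages (exact two-sided permutation p = 0.3), but the sets were defined from colony replicates 1 and 3, so this says nothing on a part played by the life stage, which stays open. A candidate explanation is that each library holds 2 RNA populations, for example from different cells or organisms in the culture, in varying proportion. If each had a fixed profile, no feature came from both and every feature was put in the right set, little correlation between the 2 contrasts would be expected within a set. The r was -0.01 in the second set but -0.3252 in the first, against -0.70 over all features. Features present in both populations could also give such a correlation. So could features put in the wrong set, or the 0.5 added to CPM where counts are low. This test therefore cannot decide and the explanation stays open. A coordinated program of a single organism also stays open, as no names or sequences were at hand to test it.

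The sets were cut on the ratio of colony replicates 3 and 1. Scaling within them therefore takes out part of the spread within colonies by construction, which could favour splits that keep these libraries together. The values that follow are given without a reading of their order. Normalizing each set separately lowered the common dispersion from 0.452 to 0.176 over the same 28653 features. The calls nonetheless went from 22 to 0, with a smallest edgeR adjusted p of 0.177. The fitted log2 differences of Cluster-41388.13838 and Cluster-41388.28064 did not shrink, at 7.29 and 5.12 before and 7.97 and 5.76 after. The share of features under an unadjusted p of 0.05 rose from 6.77% to 11.73% for the stage split. Of the 10 splits of the 6 libraries, 1 gave as large a share, and the highest other was 9.434%. With 10 splits no share under 0.05 can be reached. For the 8 calls of the main test, 3 of the 10 splits gave as many, the highest other being 24, and the same limit of 10 splits holds. The split with 24 calls set colony replicates 1 and 2 and single-cell replicate 3 against the others. After normalization within sets it gave 0 calls, as did all 10 splits, and 1.10% of features under an unadjusted p of 0.05, against 11.73% for the stage split. Splits that part colony replicates 1 and 3 ranged from 0.817% to 9.434%. The other splits that keep them together ranged from 1.28% to 5.26%.

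A small group of features parted the libraries in the same way as the split with 24 calls. In 23 features, colony replicate 3 and single-cell replicates 1 and 2 each had at least 10 counts while the other 3 libraries had 0; the reverse held for 1 feature. Over the 74 features with 0 counts in those 3 libraries and at least 20 in single-cell replicate 2, single-cell replicate 1 had 40.5% as many counts and colony replicate 3 had 8.75%. The ratio between single-cell replicates 1 and 2 had a chi-square of 1.81 per degree of freedom. Counting error alone would give about 1, so this ratio was not fixed up to counting error either. It varied far less than in 1000 sets of other features matched on count, with a median of 23.1 and a lowest value of 14.9. For these 2 libraries, 1 shared source of RNA in differing amounts could give so steady a ratio, though not all of its spread by counting error. Such a source could be carry-over from another library or an organism in some cultures, which the counts do not tell apart. Colony replicate 3 also goes against the same source at a ratio fixed up to counting error: 34 of the 74 features were at 0 there, where counting error would leave 2.88 ± 1.60 (SD). Its chi-square of 5.69 per degree of freedom nonetheless lay below all its matched sets, whose median was 26.6 and lowest value 16.2. Whether colony replicate 3 holds part of the same source thus stays open.

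Of the 74 features, 65 lie outside the largest identifier prefix, and their prefix numbers run from 44356 to 48751. Outside the largest prefix, 96.4% of the 50504 features with a prefix number under 44000 had 0 counts in all 6 libraries, against 2.89% of the 32310 features with a number of 52000 or more. The 74 features held 0.0233% of the counts of single-cell replicate 2.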
